A study of Mus musculus with 17 samples.

How the data were processed

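Total RNA of mouse bone marrow-derived macrophages was sequenced in 17 libraries, in 6 groups. Per the labels, cells of the C57BL/6J strain formed a control group (3 libraries), a group given medium conditioned by B16F10 melanoma cells (3 libraries), and groups given that medium with added KCl (3 libraries) or NaCl (2 libraries). Treatment lasted 6 hours and each salt was at 40 mM at the end. The other 6 libraries came from cells in conditioned medium with KCl made isotonic, either with floxed Kcnj2 (3 libraries) or with floxed Kcnj2 and the Lyz2-Cre driver, named the Kcnj2 knockout here (3 libraries). Groups were taken from the treatment and strain labels. What the control cells received is not stated in the labels.

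The deposited table holds raw counts per Ensembl mouse gene identifier, one column per library, and all columns matched a sample title. It was used as the authors made it. The aligner, the counting program, the genome build and the strand setting are not given in the sources used here. DESeq2 1.30.1 is named per the submitters' processing notes, with no role stated. The table lists 55401 identifiers, of which 28418 had a count of 0 in every library. The 260 identifiers without a symbol in the annotation held 0.0121% of all counts and were kept as genes. Symbols, positions, transcript lengths and GC content came from GENCODE M21 on GRCm38. Library totals ran from 13503869 to 19391623 counts, and a gene at 0 counts in a library is below 3 counts there (a limit of counting error alone).

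Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust dispersion, TMM factors, default low-count filter by group). The 11 C57BL/6J libraries were fitted together with 1 mean per group, and the 6 isotonic libraries were fitted alone. Of the genes, 14519 and 12782 passed the filter in these fits. Adjusted p is the Benjamini-Hochberg value over all genes tested in a comparison, with a threshold of 0.05. Levels are counts relative to the library total (CPM) scaled by TMM over all 17 libraries, as mean ± SD, and SE is the standard error of a log2 fold change. That replicates came from separate animals or cultures is not stated, so p-values measure only the spread between these samples, which may be technical. Counts of no pair of replicates agreed within sampling noise (chi-square per degree of freedom 2.08 to 146 over 16 pairs), so none was treated as a repeat. This value was 31.5 to 98.6 with KCl and 2.08 to 5.83 in control, conditioned medium and NaCl. The shared fit assumes 1 spread per gene in all these groups, so it can understate the spread with KCl. Residuals correlated above 0.1 in 4 of 15 same-number pairs and 1 of 30 different-number pairs of the C57BL/6J libraries. In the isotonic libraries they did so in 1 of 3 same-number and 3 of 6 different-number pairs. The library of the same number was the best match in 19 of 36 cases. A partial pairing by replicate number is thus possible in the C57BL/6J libraries. No block was used in the reported fits, and the block is among the alternatives.

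Gene lists were fixed before the data were examined, 27 of pathways and 10 of cell type markers, with 749 symbols of which 734 matched. The 33 lists with at least 5 tested genes were tested with camera of limma 3.58.1, 2-sided, at a preset inter-gene correlation of 0.01, and adjusted over these lists. Camera asks whether a list's genes rank above or below all other genes. It was repeated with a correlation estimated from the data, and fry was run as another test. Another 6 sets were chosen in 1 comparison (adjusted p under 0.05 and at least 2-fold) and tested between other libraries, adjusted as 1 family of 6. Sets chosen between conditioned medium and control came from the shared fit. The KCl and NaCl libraries they were tested in thus entered the filter and the spread used in that choice, but not the 2 means compared. Median fold changes of a list run over its tested members.

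The comparisons, tests, lists, alternatives and the rule for naming genes were also chosen before the data were examined. The rule names, per comparison, Kcnj2, Arg1, Mrc1, Nos2, Tnf, Il1b, Il6 and Vegfa where tested. It adds the 6 highest and the 6 lowest fold changes past the threshold with a mean of at least 10 CPM in a group and no overlap between the libraries of both groups. Predicted genes, Rik clones, pseudogenes and genes without symbols are left out there. Last, it takes up to 4 changed members, by smallest p, of each of the 6 lists with the smallest camera p among those past the threshold or with at least 5 changed members. For the knockout, Kcnj2 and Lyz2 are given first. The rule did not say which CPM it meant: TMM-scaled and plain CPM gave the same 12 genes by fold change in each C57BL/6J comparison and the same 2 in the knockout. Genes outside the rule are named as such.

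Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a stricter one (1 CPM in 3 libraries and a mean of 20 counts), only the groups compared, all 17 libraries in a single fit, the replicate number as a block, a 2-fold minimum, other set tests, other set definitions and leaving out each replicate. DESeq2 was not applied to gene lists, since camera here works on the edgeR fit. Added after seeing the data were total-count scaling, leaving out libraries of extreme length slope, and 3 covariates: the transcript-length slope, the GC slope and the stromal marker level. The length slope is the regression slope of a library's log2 CPM, as deviation from the mean over groups, on log2 transcript length in SD units, with GC content in the same regression, over 8541 genes with mean log2 CPM above 3.

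The tests were checked on simulated data, drawn from the mean and spread of each gene, in which 200 genes were changed. The shares recovered by edgeR at 1.5-, 2- and 4-fold were 50.8%, 61.2% and 93.8% for conditioned medium against control and 49.3%, 78.5% and 90.6% for KCl against conditioned medium. They were 32.8%, 76.9% and 93.8% for NaCl against conditioned medium, 34.4%, 62.1% and 89.4% for KCl against NaCl, and 0%, 39.1% and 73.4% for the knockout. False calls numbered 18, 14, 9, 3 and 4 in that order. Camera called a set of 50 genes shifted by 0.5 on the log2 scale in each comparison and called 0 of 20 unchanged sets. Genes were drawn independently of each other there. The 0 of 20 thus does not show how often camera calls unchanged lists whose genes vary together.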

Results

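RNA of macrophages was measured in 17 libraries in 6 groups: 3 control, 3 given melanoma-conditioned medium, 3 given conditioned medium with KCl, 2 given conditioned medium with NaCl, and 3 with floxed Kcnj2 and 3 with Kcnj2 knockout in conditioned medium with isotonic KCl. B16F10 is a mouse melanoma line, and conditioned medium is medium in which such cells have grown. Total counts per library were 16524448 to 18511570 in control, 15458703 to 16460805 in conditioned medium, 13503869 to 17048265 with KCl and 17499587 to 19391623 with NaCl. They were 15618236 to 16994998 in floxed and 16223709 to 17095003 in knockout cells. Libraries also differed in how counts followed transcript length. The length slope ran from 0.02 to 0.07 in control, 0.03 to 0.08 in conditioned medium, −0.11 to 0.02 with KCl, 0.07 to 0.11 with NaCl, −0.17 to 0.10 in floxed and −0.13 to −0.01 in knockout cells. Of the markers of melanoma cells, Tyr had 0 counts in each of the 17 libraries, and Gpnmb, which macrophages also express, made up most of the list's counts. That list had too few tested genes for a test. None of the 6 cell type lists tested passed the threshold in any of the 4 comparisons of C57BL/6J cells, but neutrophil markers moved with the treatments: their summed level was 64.1 to 64.8 CPM in control, 180 to 194 CPM in conditioned medium, 46.9 to 55.0 CPM with KCl and 70.1 to 71.1 CPM with NaCl. In conditioned medium against control 4 of these 8 markers rose and 2 fell (the same adjusted over the list alone, median 0.92, adjusted p = 0.110), and the list passed without control 1 (0.0374, median 1.59) or control 2 (0.0328, median 1.58). Stromal markers passed as lower with KCl than with NaCl without KCl 3 (0.0143). Neutrophil markers passed, with the length slope as a covariate, as lower with KCl than in conditioned medium alone (0 of 8 up, 4 down, median −0.77, adjusted p = 0.00972, and adjusted p = 0.125 with an estimated correlation) and than with NaCl (0 up, 2 down, median −0.44, adjusted p = 0.0245, and 0.140 with an estimated correlation). With that covariate macrophage identity markers passed as lower with NaCl than in conditioned medium alone (1 of 12 up, 7 down, median −0.23, adjusted p = 0.00891, and 0.175 with an estimated correlation).

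Conditioned medium against control asked how the macrophages respond to factors shed by the melanoma cells. Genes of inflammation rose the most. Tnf, an inflammatory cytokine, rose from 24.4 ± 1.38 to 2651 ± 30.1 CPM (n = 3 and 3, log2 fold change 6.75, SE 0.09, adjusted p = 3.7e-15). Il1b, the precursor of interleukin-1 beta, rose from 22.1 ± 2.45 to 3897 ± 198 CPM (log2 fold change 7.45, SE 0.11, adjusted p = 1.8e-14). Kcnj2, which encodes the inward rectifier potassium channel Kir2.1, rose from 38.5 ± 2.89 to 80.1 ± 1.66 CPM (log2 fold change 1.05, SE 0.09, adjusted p = 2.7e-07).

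Among the genes with the highest fold changes in conditioned medium were the neutrophil chemokines Cxcl2 (9.13), Cxcl3 (9.09) and Cxcl1 (8.31), the cytokine Il1a (8.14), Acod1, which makes itaconate (7.69), and Shisa3 (8.59). The lowest were the G protein signalling regulator Rgs2 (−6.14), Il11 (−5.93), the transporter Slco2b1 (−5.41), the chemokine receptors Cxcr4 (−5.27) and Cx3cr1 (−5.23), and Pald1 (−4.74). The cytokine Il6 rose (7.35, SE 0.37), as did Nos2, the inducible nitric oxide synthase (6.98, SE 0.44), which stood near 0 counts in control cells. Mrc1, the mannose receptor of alternatively activated macrophages, fell (−0.50, SE 0.10, adjusted p = 9.9e-04). For Vegfa, a growth factor of blood vessels, the log2 fold change was −0.17 (SE 0.08, adjusted p = 0.098).

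Of 23 pro-inflammatory markers tested, 20 rose and 1 fell in conditioned medium (20 and 2 adjusted over the list alone), with a median log2 fold change of 5.97 (camera adjusted p = 3.5e-64). They include the chemokine Ccl3 (7.48). All 22 NF-kB feedback and target genes rose (22 adjusted over the list alone, median 2.68, adjusted p = 1.2e-49), among them Malt1 (4.08), Tnfaip3 (4.33), Sod2 (3.89) and Traf1 (3.75). Of 32 interferon-stimulated genes, 31 rose (31 adjusted over the list alone, median 2.13, adjusted p = 5.7e-26), with the guanylate-binding proteins Gbp5 (6.94), Gbp2 (4.58) and Gbp3 (3.06) and the antiviral gene Rsad2 (3.69). Among 17 targets of NRF2, the regulator of antioxidant genes, 14 rose (14 adjusted over the list alone, median 0.97, adjusted p = 2.2e-12), such as the cystine transporter Slc7a11 (6.13), the haem oxygenase Hmox1 (2.65), Gsr (2.60) and Srxn1 (2.45). The ATF4 list of the integrated stress response had 15 of 18 genes higher and 2 lower (15 and 2 adjusted over the list alone, median 1.45, adjusted p = 4.2e-11), with Gdf15 (4.69), Ppp1r15a (3.28) and Mthfd2 (2.89). Cholesterol synthesis and uptake had 20 of 23 genes higher and 3 lower (20 and 3 adjusted over the list alone, median 1.16, adjusted p = 7.0e-09), including Sc5d (1.48) and Mvd (1.48).

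Cell cycle genes moved the other way: 27 of 34 fell and 1 rose (29 and 1 adjusted over the list alone, median −0.73, adjusted p = 1.9e-07). Lists given here with a single set of counts had the same counts adjusted over the list alone. Other lists that ranked higher in conditioned medium were inflammasome components (10 of 16 up, 4 down, median 0.71, adjusted p = 3.4e-05), hypoxia and HIF1 targets (16 of 22 up, 3 down, 16 and 4 adjusted over the list alone, median 0.81, adjusted p = 3.0e-04) and arginine and polyamine metabolism (8 of 16 up, 3 down, median 0.40, adjusted p = 0.00685). These lists and the 6 above stayed past the threshold with an estimated correlation. Another 5 did not. MHC class I presentation had 18 of 21 genes up and 1 down (median 0.73, adjusted p = 9.4e-06, and adjusted p = 0.063 with an estimated correlation). Glycolysis had 15 of 22 up and 3 down (median 0.79, adjusted p = 3.5e-04), and amino acid metabolism 13 of 25 up and 5 down (median 0.53, adjusted p = 0.0018). Ribosome biogenesis had 20 of 30 up and 2 down (21 and 2 adjusted over the list alone, median 0.49, adjusted p = 0.0183). Each of these last 3 lists had an adjusted p = 0.201 with an estimated correlation. Alternative activation markers had 9 of 20 up and 6 down (median 0.09, mean 0.76, adjusted p = 0.0459, and adjusted p = 0.238 with an estimated correlation), and this call was lost without control 1 (0.0588), control 2 (0.0654) or control 3 (0.057), its median running from −0.07 without conditioned medium library 1 to 0.30 without control 1. It was also lost with the length slope as a covariate (0.0804).

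In total 7773 of 14519 genes tested changed between conditioned medium and control, 3945 higher and 3828 lower, and 3046 by at least 2-fold. DESeq2 called 7751, of which 7639 were also called by edgeR with the same direction. The TMM factors were 1.24 to 1.25 in control and 0.97 to 0.99 in conditioned medium, so total-count scaling shifts the median of all genes by −0.34, and 24.9% of called genes are then higher in place of 50.8%. That shift exceeds the median of the alternative activation list.

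**Figure D1:**
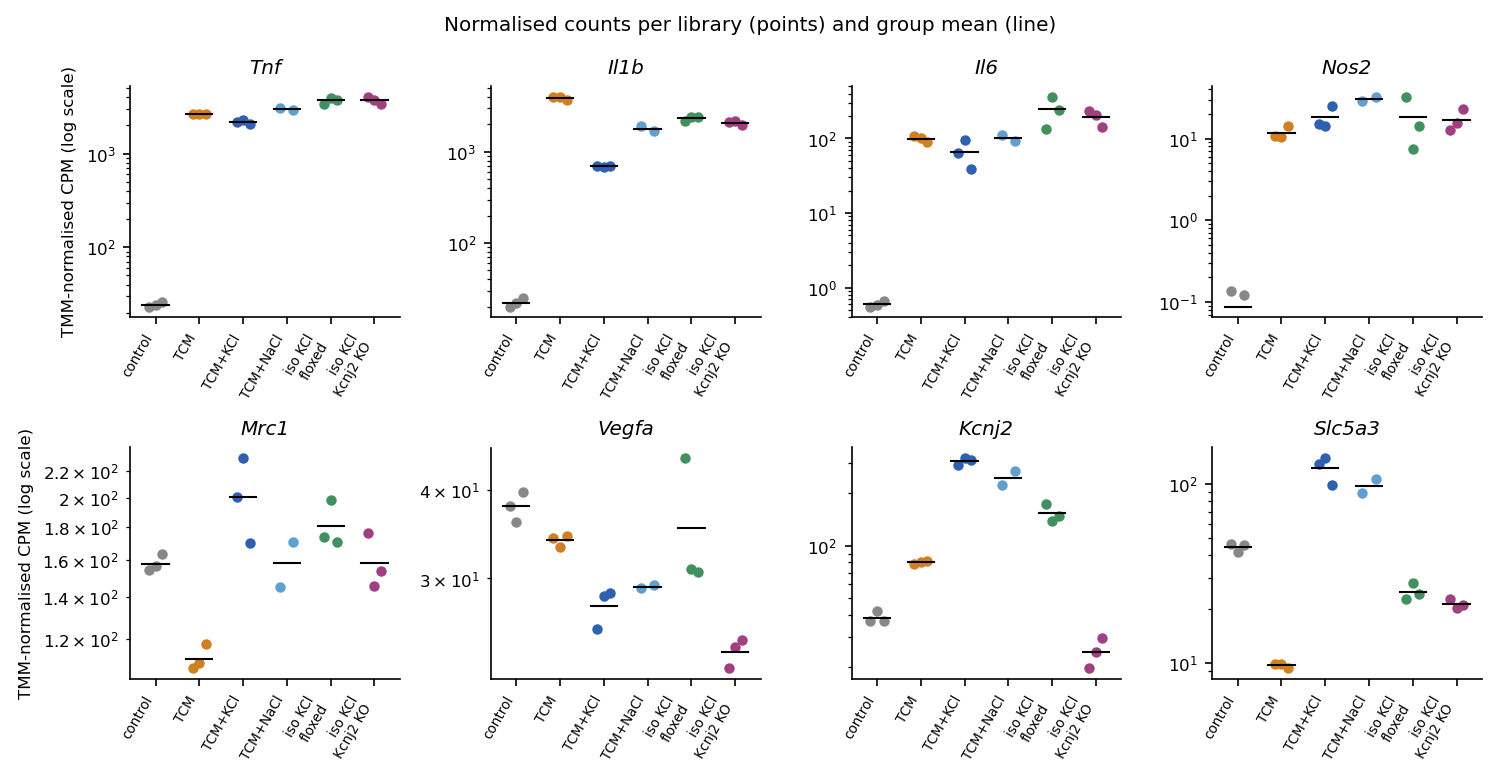
TMM-scaled CPM (log axis) of 8 genes in each of the 17 libraries (points), with the group mean as a line. A control library with 0 counts of Nos2 cannot be drawn on the log axis. Tnf and Il1b are far higher in conditioned medium than in control, and Kcnj2 is highest with KCl and lowest in the knockout.

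KCl in conditioned medium against conditioned medium alone asked what potassium at 40 mM adds. Il1b fell from 3897 ± 198 to 700 ± 8.36 CPM (n = 3 and 3, log2 fold change −2.49, SE 0.09, adjusted p = 3.1e-10). Kcnj2 rose from 80.1 ± 1.66 to 307 ± 13.9 CPM (log2 fold change 1.93, SE 0.09, adjusted p = 3.5e-09). Slc5a3, which imports the osmolyte myo-inositol, rose from 9.71 ± 0.348 to 123 ± 21.3 CPM (log2 fold change 3.65, SE 0.13, adjusted p = 4.3e-10). The scavenger receptor Marco fell from 950 ± 57.8 to 72.9 ± 17.5 CPM (log2 fold change −3.72, SE 0.15, adjusted p = 1.7e-09).

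Tnf (−0.28, SE 0.07, adjusted p = 0.00277) and Vegfa (−0.32, SE 0.08, adjusted p = 0.00533) fell with KCl, and Mrc1 rose (0.83, SE 0.10). The genes highest by fold change were Rn7sk (3.81), Scgb1a1, a secretoglobin typical of airway (3.79), Slc5a3, the transporter Slco4a1 (3.62), the chemokine receptor Xcr1 (3.61) and CT010467.1 (3.06). The lowest were Tifab (−4.92), the dicarboxylate transporter Slc13a3 (−4.55), the Src-family kinase Fgr (−4.27), Gbgt1 (−3.85), Cd300e (−3.84) and Marco. Of these, Rn7sk and CT010467.1 rested on KCl library 2: without it their log2 fold changes were 0.84 and 0.45. The call on Rn7sk was lost without any 1 of the conditioned medium libraries (adjusted p 0.0774 to 0.0972), and that on CT010467.1 without any of them or KCl library 2 (0.10 to 0.117). Il6 stood at −0.60 (SE 0.23, adjusted p = 0.0495) and Nos2 at 0.62 (SE 0.22, adjusted p = 0.0315). The call on Il6 was lost without any conditioned medium library, KCl library 1 or KCl library 3 (0.0547 to 0.117), its fold change being −0.94 without KCl library 2 and −0.33 without KCl library 3. The call on Nos2 was lost without conditioned medium library 1 (0.0979), library 2 (0.11) or KCl library 3 (0.105, at a log2 fold change of 0.31).

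Osmolyte genes rose together with KCl: of 17 targets of NFAT5, the regulator of the response to hypertonic stress, 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.70, adjusted p = 1.1e-08). Besides Slc5a3 these include the betaine transporter Slc6a12 (2.02), the aldose reductase Akr1b3 (2.02) and the amino acid transporter Slc38a2 (1.98). Of 17 NRF2 targets, 13 rose (13 adjusted over the list alone, median 0.68, adjusted p = 3.8e-08), such as Gclc (2.09) and Gclm (0.86), the subunits of the enzyme limiting glutathione synthesis, Slc7a11 (1.30) and Hmox1 (1.25). Both lists stayed past the threshold with an estimated correlation. Amino acid metabolism had 14 of 25 genes up and 4 down (median 0.44, adjusted p = 2.5e-04, and adjusted p = 0.214 with an estimated correlation), with the glutamine synthetase Glul at 1.34. The ATF4 list had 10 of 18 up and 2 down (median 0.38, adjusted p = 0.0129, and adjusted p = 0.138 with an estimated correlation), with Atf4 itself (1.72), Gdf15 (1.26) and Cebpg (0.59).

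Lysosomal genes had 17 of 29 up and 3 down with KCl (18 and 3 adjusted over the list alone, median 0.33, adjusted p = 0.010, and adjusted p = 0.138 with an estimated correlation), with Sqstm1 (1.03) and the proton pump subunits Atp6v0d2 (0.94) and Atp6v1a (0.73) up and the protease Ctsc (−0.80) down. Inflammasome components had 11 of 16 down and 4 up (median −0.99, adjusted p = 0.0258, and adjusted p = 0.214 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation had 48 of 68 up and 3 down (48 and 4 adjusted over the list alone, median 0.66, adjusted p = 2.1e-05, and adjusted p = 0.545 with an estimated correlation), such as Cox7b (0.84), Ndufs8 (0.76), Atp5o (0.73) and Cox5b (0.49). The length slopes of the KCl libraries, −0.11 to 0.02, moved with this list, and with the slope as a covariate its median was 0.12 (adjusted p = 0.334). Pro-inflammatory markers, which did not pass with KCl (8 of 23 up and 12 down, 9 and 12 adjusted over the list alone, median −0.28, adjusted p = 0.0716), passed as lower with that covariate (median −0.35, adjusted p = 0.00166, and adjusted p = 0.326 with an estimated correlation). They also passed without conditioned medium library 3 (0.0465) or KCl library 1 (0.0461). Alternative activation markers (median −0.37, adjusted p = 0.0716) passed as lower without KCl library 1 (0.0407) or 3 (0.0406).

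KCl changed 7830 of 14519 genes, 3857 higher and 3973 lower, and 2759 by at least 2-fold. DESeq2 called 7918, with 7642 shared in direction. With the length slope as a covariate 5994 genes were called, of which 4965 were called with the same direction before. Slopes did not overlap between these groups (−0.11 to 0.02 with KCl, 0.03 to 0.08 in conditioned medium). The covariate thus takes up part of any KCl effect, so the lost calls cannot tell a length bias from such an effect. Total-count scaling shifts the median of all genes by −0.21, with 32.6% of called genes higher in place of 49.3%. With KCl library 3 alone, the only KCl library with a slope above 0, the count was 6845, in a fit in which that lone library is assumed to vary like the other groups.

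NaCl in conditioned medium against conditioned medium alone is the control for salt and osmolarity at the same 40 mM. Kcnj2 rose here too, from 80.1 ± 1.66 to 245 ± 31.2 CPM (n = 3 and 2, log2 fold change 1.62, SE 0.09, adjusted p = 1.1e-07). Il1b fell from 3897 ± 198 to 1802 ± 154 CPM (log2 fold change −1.11, SE 0.10, adjusted p = 3.4e-06). Slc5a3 rose from 9.71 ± 0.348 to 97.8 ± 12.6 CPM (log2 fold change 3.34, SE 0.14, adjusted p = 7.3e-09). Nos2 rose (1.38, SE 0.24), as did Mrc1 (0.50, SE 0.11, adjusted p = 0.00473), whose call was lost without NaCl library 2 (0.0956). Log2 fold changes of Tnf (0.19, adjusted p = 0.0674), Vegfa (−0.21, adjusted p = 0.103) and Il6 (0.03, adjusted p = 0.943) did not pass.

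The highest fold changes with NaCl were those of Slco4a1 (3.58), Slc5a3, Slc6a12 (2.61), the costimulatory receptor Cd28 (2.51), Gclc (2.40) and the adaptor Shb (2.29). The lowest were those of Slc13a3 (−3.47), Tifab (−3.29), Fgr (−3.27), Marco (−2.93), Fgl2 (−2.86) and Ppm1n (−2.79). NFAT5 targets had 13 of 17 genes up and 1 down (13 and 1 adjusted over the list alone, median 0.87, adjusted p = 2.5e-16), with Akr1b3 (1.51) and Slc38a2 (1.44). NRF2 targets had 13 of 17 up and 0 down (13 adjusted over the list alone, median 0.86, adjusted p = 4.5e-15), with Slc7a11 (1.51), Hmox1 (1.14) and Gclm (0.86). Both lists stayed past the threshold with an estimated correlation, and the next 3 did not. Interferon-stimulated genes had 19 of 32 up and 4 down (median 0.48, adjusted p = 1.2e-06, and adjusted p = 0.169 with an estimated correlation), such as Rsad2 (1.57), Cmpk2 (1.22), Irgm1 (1.10) and Ifit2 (0.77). Amino acid metabolism had 9 of 25 up and 3 down (9 and 5 adjusted over the list alone, median 0.22, adjusted p = 3.5e-06, and adjusted p = 0.169 with an estimated correlation), with Glul at 1.41. Heat shock genes had 5 of 16 up and 1 down (median 0.17, adjusted p = 0.0294, and adjusted p = 0.26 with an estimated correlation), and this call was lost without conditioned medium library 3 (0.0538). Its changed members include the chaperones Hspa1b (1.46), Hspa4l (1.05), Dnajb4 (0.81) and Hspa1a (0.78), the last of which lost its call without NaCl library 1 (0.0647) or 2 (0.052). Of 23 genes of cholesterol synthesis and uptake, 8 fell and 0 rose (8 and 1 adjusted over the list alone, median −0.23, adjusted p = 0.0608), such as Mvk (−1.17), Pmvk (−0.97), Hsd17b7 (−0.64) and Hmgcs1 (−0.47). This list passed as lower with the length slope as a covariate (median −0.13, adjusted p = 0.0398, and adjusted p = 0.25 with an estimated correlation), as did alternative activation markers (median −0.31, adjusted p = 0.0496, and 0.25 with an estimated correlation).

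NaCl changed 4161 of 14519 genes, 1996 higher and 2165 lower, and 1013 by at least 2-fold. DESeq2 called 4376, with 4111 shared in direction. The edgeR count was 2602 without NaCl library 1 and 2224 without NaCl library 2, fits in which the lone NaCl library is assumed to vary like the other groups. Under total-count scaling 37.0% of called genes were higher, in place of 48.0%.

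Both salts changed 3387 genes alike, 1535 higher and 1852 lower, and 27 in opposite directions. Independent lists of these sizes would share 530 higher and 592 lower. Since both comparisons use the same 3 conditioned medium libraries, the overlap is not independent. In 20 simulations of unchanged groups 0 genes were called alike by edgeR. With no true change few calls can arise at all, so this does not show how much sharing adds to the overlap. Fold changes in these simulations still correlated at 0.43, against 0.62 in the data. Their covariance was 0.43 in the data and 0.054 in the simulations. Without NaCl library 2 the count of genes changed alike was 2045, and with a 2-fold minimum it was 764.

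**Figure D2:**
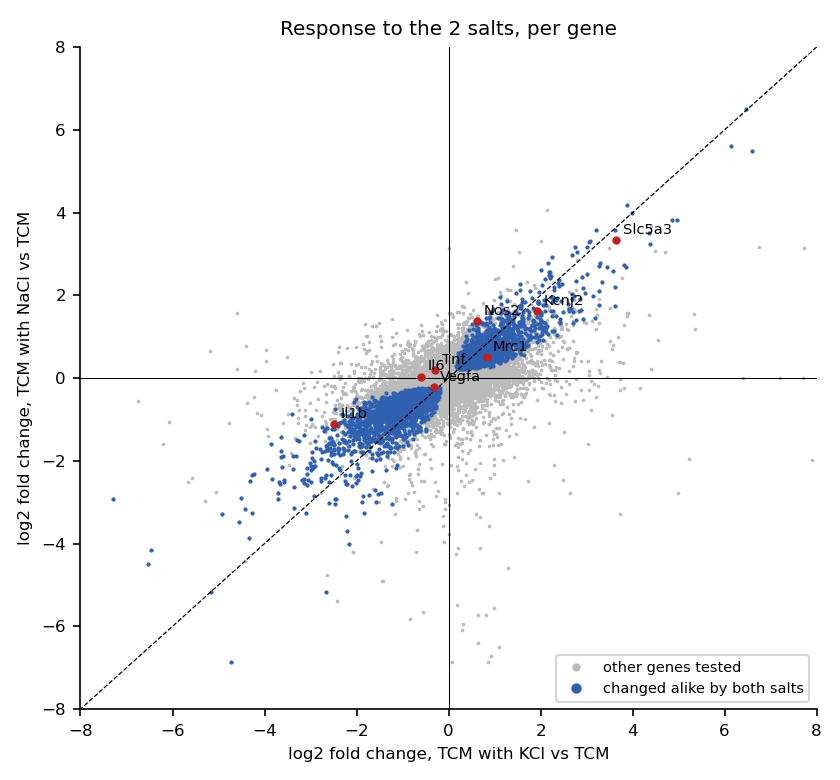
Log2 fold change of each tested gene with KCl (horizontal axis) and with NaCl (vertical axis), both against conditioned medium alone. The dashed line marks equal changes, blue points are the 3387 genes changed alike, and red points are named genes. Slc5a3 and Kcnj2 lie high on both axes, and Il1b lies lower with KCl (−2.49) than with NaCl (−1.11).

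KCl against NaCl tests the difference between the salts, with 3 and 2 libraries. Il1b was lower with KCl, at 700 ± 8.36 against 1802 ± 154 CPM (n = 3 and 2, log2 fold change −1.38, SE 0.09, adjusted p = 5.2e-06). Tnf was lower too, at 2192 ± 103 against 3020 ± 92.6 CPM (log2 fold change −0.48, SE 0.07, adjusted p = 0.00126). Il1a (−1.30, SE 0.15) and the inflammasome sensor Nlrp3 (−1.35, SE 0.18) were lower, and Atf4 was higher (1.34, SE 0.15). With the length slope as a covariate each of these 5 genes stayed past the threshold with the same direction: Il1b at −1.38, Tnf at −0.58, Il1a at −0.93, Nlrp3 at −0.57 and Atf4 at 0.70. Their calls were not examined in the fit of only the KCl and NaCl libraries, which called far fewer genes in all.

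Of the genes with the largest differences between the salts, Scgb1a1 (3.42), the RNA sensor Tlr8 (−2.70), the cytoskeletal gene Vcl (−2.44) and Ntng2 (−1.51) also stayed past the threshold with that covariate. Xcr1 (1.88), Wdr89 (2.27), Nr2c2ap (2.18), Rpl35a (1.88), Atp5e (1.88), Med12 (−1.80), Atp7a (−1.72) and Atg9a (−1.60) did not. Leaving out 1 library ended the calls on Wdr89 (0.106 without NaCl 1, 0.104 without NaCl 2), Rpl35a (0.0514 and 0.0909) and Atg9a (0.0598 and 0.131). Without NaCl 2 those on Nr2c2ap (0.0909), Atp5e (0.0846), Atp7a (0.0567), Med12 (0.11) and the ATF4 list member Ddit3 (0.0503) ended too. Without KCl 2, Wdr89 stood at 1.42, Nr2c2ap at 1.40 and Rpl35a at 1.22, and without KCl 3 Atg9a stood at −2.49. For Kcnj2 the log2 fold change was 0.31 (SE 0.10, adjusted p = 0.0272), and 0.17 without NaCl 1 (0.303). For Nos2 it was −0.75 (adjusted p = 0.0289), a call lost without KCl 1 (0.0979), KCl 2 (0.056), NaCl 1 (0.0831) or NaCl 2 (0.182). For Mrc1 it was 0.33 (adjusted p = 0.0457), a call lost without KCl 1 (0.0984), KCl 2 (0.106), NaCl 1 (0.338, at 0.20) or NaCl 2 (0.073). Il6 (−0.63, adjusted p = 0.0825) and Vegfa (−0.11, adjusted p = 0.397) did not pass, though Il6 did without KCl 2 (−0.98, adjusted p = 0.00267). With the length slope as a covariate the sign of Nos2 turned, to 0.20.

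No list passed the threshold between the salts with an estimated correlation. With the preset one, oxidative phosphorylation had 56 of 68 genes higher with KCl and 1 lower (58 and 2 adjusted over the list alone, median 0.77, adjusted p = 7.2e-19, and adjusted p = 0.596 with an estimated correlation), with Ndufb11 (0.91), Ndufa7 (0.82), Ndufs8 (0.77) and Cox5b (0.58). Length slopes differed the same way, −0.11 to 0.02 with KCl and 0.07 to 0.11 with NaCl, and with the slope as a covariate the list's median was 0.03 (adjusted p = 0.616). Interferon-stimulated genes had 13 of 32 lower and 1 higher (15 and 2 adjusted over the list alone, median −0.32, adjusted p = 2.7e-04, and adjusted p = 0.38 with an estimated correlation), with Oasl1 (−1.20), Mx1 (−1.20), Gbp7 (−0.84) and Gbp5 (−0.77). The ATF4 list had 9 of 18 higher (11 higher and 3 lower adjusted over the list alone, median 0.36, adjusted p = 0.00455, and adjusted p = 0.216 with an estimated correlation), with Trib3 (1.04), Gdf15 (0.77) and Ddit3 (0.65).

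Pro-inflammatory markers had 9 of 23 lower and 2 higher with KCl (9 and 3 adjusted over the list alone, median −0.21, adjusted p = 0.011, and adjusted p = 0.688 with an estimated correlation), with Il12b at −1.73. This call was lost without KCl 3 (0.171) or NaCl 1 (0.06), and the median was −0.32 without KCl 2 and −0.33 without NaCl 2. Of its members 11 were lower and 0 higher with the length slope as a covariate, with a median of −0.58 (adjusted p = 2.5e-13, and adjusted p = 0.0895 with an estimated correlation). Inflammasome components had 7 of 16 lower and 1 higher (7 and 2 adjusted over the list alone, median −0.32, adjusted p = 0.0224, and adjusted p = 0.38 with an estimated correlation), with Mefv (−0.76) lower and Casp4 (0.44) higher. Among 29 lysosomal genes 13 were higher and 2 lower (13 and 2 adjusted over the list alone, median 0.20), with the proteases Ctsd (0.61), Ctsl (0.57) and Ctsz (0.48) higher and Ctsc (−0.61) lower. This list did not pass (adjusted p = 0.0527, and adjusted p = 0.38 with an estimated correlation), but did without KCl 1 (0.0415) or KCl 2 (0.00316) and with the length slope as a covariate (median 0.20, adjusted p = 7.5e-05, and 0.140 with an estimated correlation). NFAT5 targets did not pass (4 of 17 higher and 2 lower, 4 and 4 adjusted over the list alone, median −0.05, adjusted p = 0.953). They passed as higher with KCl once the length slope was a covariate (2 higher and 0 lower, median 0.26, adjusted p = 0.00299, and adjusted p = 0.0895 with an estimated correlation), as did amino acid metabolism (4 of 25 higher and 0 lower, median 0.22, adjusted p = 6.5e-04, and 0.0895 with an estimated correlation). The 1389 genes raised at least 2-fold by conditioned medium were lower with KCl than with NaCl, with a median of −0.23, 928 of them below 0 (camera adjusted p = 7.9e-06, and adjusted p = 0.00237 with an estimated correlation). The 1657 genes lowered by it had a median of 0.03 (adjusted p = 0.226).

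Between the salts 4591 of 14519 genes differed, 2233 higher and 2358 lower with KCl, and 881 by at least 2-fold. This count is fragile: it was 960 without NaCl 2, 2103 without NaCl 1, 3018 without KCl 1 and 6989 without KCl 3, and 8 when only these 5 libraries were fitted. With the length slope as a covariate 525 genes differed, of which 303 were called with the same direction before. DESeq2 called 4910, with 4473 shared in direction, and total-count scaling left 30.1% of called genes higher in place of 48.6%, with a shift of −0.14.

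**Figure D3:**
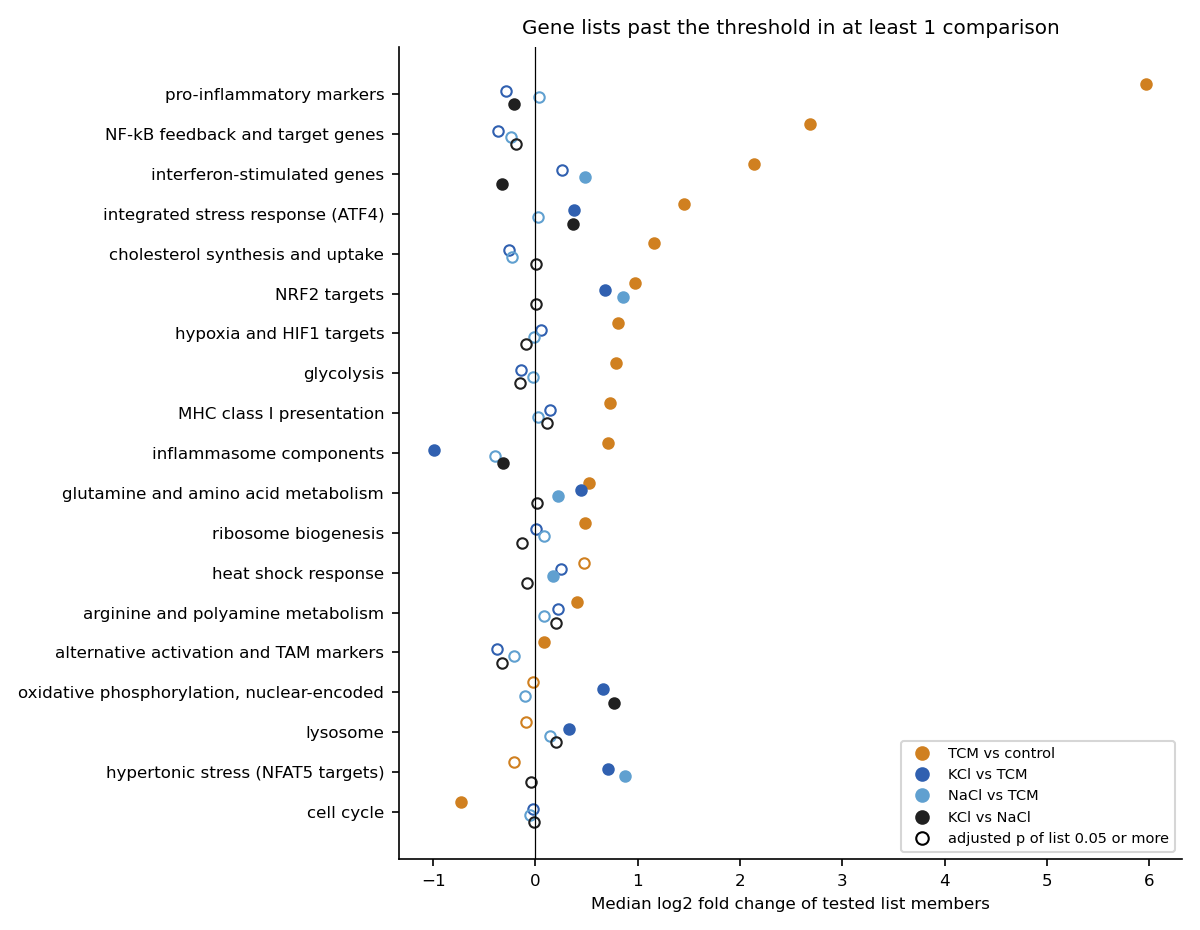
Median log2 fold change of the tested members of each list that passed the threshold in at least 1 of the 4 comparisons of C57BL/6J cells. Filled points passed at the preset correlation and open points did not. NFAT5 and NRF2 targets lie above 0 for both salts, and oxidative phosphorylation lies above 0 in both comparisons of KCl.

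Kcnj2 knockout against floxed cells in isotonic KCl asked which genes differ when the channel gene is deleted with Lyz2-Cre. Per the strain labels the floxed cells carry no Cre driver. Loss of the channel therefore cannot be told apart from effects of Cre, of the altered Lyz2 locus or of other strain differences. Kcnj2 (ENSMUSG00000041695, GRCm38 chromosome 11, 111066164 to 111076821, plus strand) fell from 153 ± 17.6 to 24.5 ± 4.86 CPM (n = 3 and 3, log2 fold change −2.64, SE 0.19, adjusted p = 0.015). Its levels were 19.7, 24.4 and 29.4 CPM in the knockout libraries and 173, 139 and 147 CPM in the floxed ones. Lyz1, a lysozyme gene, rose from 28.7 ± 5.06 to 149 ± 15.7 CPM (log2 fold change 2.38, SE 0.17, adjusted p = 0.015). Its neighbour Lyz2, the locus that carries the Cre driver, stood at 22461 ± 2394 CPM in floxed and 7648 ± 638 CPM in knockout cells (log2 fold change −1.55, SE 0.15, adjusted p = 0.0593), which did not pass the threshold. In the other groups Lyz2 lay between 20299 and 23311 CPM. Lyz1 and Lyz2 (chromosome 10, 117287797 to 117292868 and 117277331 to 117282321, both minus strand) are close paralogs, and how reads shared by them were counted is not given; their sum was 22490 ± 2399 CPM in floxed and 7797 ± 650 CPM in knockout cells.

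Kcnj2 and Lyz1 were the only 2 of 12782 genes called by edgeR, with 716 at an unadjusted p under 0.05 and 177 called by DESeq2. With no true change a share of 0.05 of all genes tested is expected at such a p, and 716 is not far above that. Adjusted p values of Kcnj2 and Lyz1 rose above 0.05 without floxed library 3 (0.389 for each) and without any knockout library (0.058 to 0.346). Without floxed library 1, 14 genes were called. With the replicate numbers as a block 0 genes were called, and both had an adjusted p = 0.263. Floxed libraries had length slopes from −0.17 to 0.10, and with the slope as a covariate 1043 genes were called, 469 higher and 574 lower. With that covariate Lyz2 fell (−1.58, SE 0.05), as did Marco (−0.91, SE 0.05), the smooth muscle actin Acta2 (−0.93, SE 0.05), the chemokine Cxcl5 (−1.05, SE 0.06) and Ptx3 (−1.44, SE 0.07), genes chosen after their values were seen. Log2 fold changes without it were −0.57 for Vegfa, −0.34 for Il6, −0.19 for Mrc1, −0.17 for Il1b, −0.10 for Nos2 and 0.02 for Tnf, none past the threshold (adjusted p = 0.519 for Vegfa and 1.0 for the others). Arg1, the arginase of alternatively activated macrophages, had 0 to 9 counts per library in the whole series and was not tested.

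Markers of other cell types differed between knockout and floxed cells. Of 12 stromal markers, 0 were called over all genes and 11 were lower adjusted over the list alone (median −0.97, adjusted p = 1.1e-23, and adjusted p = 0.109 with an estimated correlation). Their summed level was 1042, 685 and 805 CPM in floxed and 427, 410 and 514 CPM in knockout libraries. B cell markers had 2 of 5 higher and 1 lower adjusted over the list alone (median 0.67, mean 0.23, adjusted p = 0.00561, and adjusted p = 0.208 with an estimated correlation), with Igkc at 1.03 and Ighm at 0.94 but Ebf1 at −1.46. Megakaryocyte and platelet markers had 1 of 5 higher adjusted over the list alone and a median of 0.62 (adjusted p = 0.00561, and adjusted p = 0.175 with an estimated correlation). Without floxed library 1 the B cell median was 0.35 and the call on the megakaryocyte list was lost (0.142), and without knockout library 1 its median was 0.39.

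MHC class I genes ranked higher in the knockout (median 0.27, 4 of 21 higher adjusted over the list alone, adjusted p = 1.1e-08, and adjusted p = 0.175 with an estimated correlation), with H2-Q6 at 0.60 and H2-Q7 at 0.58. Lysosomal genes (median 0.16, adjusted p = 1.5e-04) and interferon-stimulated genes (median 0.11, adjusted p = 0.0011) ranked higher too, each with adjusted p = 0.175 with an estimated correlation. The ATF4 list ranked lower (median −0.18, 2 of 18 lower adjusted over the list alone, adjusted p = 0.00202, and adjusted p = 0.192 with an estimated correlation). Amino acid metabolism (median −0.12, adjusted p = 0.00834), cell cycle (−0.20, 0.0183), hypoxia targets (−0.09, 0.0191), NFAT5 targets (−0.11, 0.045) and p53 targets (−0.04, 0.045) ranked lower, and oxidative phosphorylation higher (0.07, 0.0232). With an estimated correlation the adjusted p of these 6 lists, in the same order, was 0.273, 0.175, 0.182, 0.267, 0.208 and 0.832. In these 10 lists 0 members were called over all genes, and of the last 6 lists, adjusted over the list alone, 1 NFAT5 target and 1 p53 target were lower. Each of the last 6 calls was lost without at least 1 library: amino acid metabolism without floxed 1 (0.119) or knockout 2 (0.114), cell cycle without floxed 1 (0.0835), floxed 2 (0.056) or knockout 3 (0.0587), and hypoxia without floxed 2 (0.0519), knockout 1 (0.0537) or knockout 3 (0.0905). That on NFAT5 targets was lost without floxed 1 (0.538), floxed 3 (0.0839) or any knockout library (0.0659 to 0.167), and that on p53 targets without any of the 6 libraries (0.0831 to 0.142). That on oxidative phosphorylation was lost without knockout 1 (0.644) or 2 (0.244) and turned over without floxed 1 (median −0.19, adjusted p = 0.00178), its median being 0.36 without floxed 2, 0.12 without floxed 3, −0.05 and 0.01 without knockout 1 and 2, and 0.22 without knockout 3. The median of NFAT5 targets was 0.04 without floxed 1, −0.22 without floxed 2, −0.07 without knockout 2 and −0.19 without knockout 3. That of p53 targets ran from −0.11 without floxed 1 to −0.03 without knockout 2, that of amino acid metabolism was −0.20 without floxed 2, and that of hypoxia targets −0.14 without knockout 3. Without floxed 1 the median of MHC class I was 0.18, and that of interferon-stimulated genes 0.17, or 0.06 without knockout 3. In all 13 lists passed, and 8 without floxed library 1. The calls on megakaryocyte markers (0.424), NFAT5 targets (0.559), p53 targets (0.0677) and oxidative phosphorylation (0.603) were lost with the length slope as a covariate, and those on the other 9 lists stayed, cell cycle the nearest to the threshold (0.0468). With it pro-inflammatory markers (median −0.05, 0.0454) and macrophage identity markers (−0.02, 0.0257) also passed as lower, and MHC class II (0.10, 0.0464) and complement and efferocytosis genes (0.11, 0.0371) as higher, but with an estimated correlation no list passed there (lowest 0.182, stromal markers). The macrophage identity list (12 tested, 2 higher and 1 lower, mean −0.09) includes Lyz2, the locus of the Cre driver, which fell with this covariate. The call thus cannot be read as a loss of macrophage identity.

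Genes that KCl had raised at least 2-fold in C57BL/6J cells had a median of 0.02 in the knockout (986 tested, adjusted p = 0.0751), and those it had lowered −0.04 (1403 tested, adjusted p = 0.475). Genes higher with KCl than with NaCl had a median of 0.01 (436 tested, ranked higher at adjusted p = 0.0194), and those lower with KCl −0.18 (317 tested, adjusted p = 0.0751). Each of these 4 sets had an adjusted p = 0.848 with an estimated correlation. All 4 turned over without floxed library 1, to −0.19, 0.08, −0.35 and 0.22. Each passed in that opposite direction there (camera adjusted p = 3.1e-05, 0.0193, 4.2e-11 and 3.1e-04). The call on the third was lost without knockout library 1 (0.781) or 2 (0.226). The median of that set was 0.45 without floxed library 2, −0.15 and −0.08 without knockout libraries 1 and 2, and 0.21 without knockout library 3. The other 3 sets passed in their first direction without floxed library 2 (0.26, −0.13 and −0.39) and without knockout library 3 (0.14, −0.11 and −0.39). Genes raised by KCl (0.04) and those lower with KCl than with NaCl (−0.25) also passed without floxed library 3, and the latter without KCl library 3 (−0.14).

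**Figure D4:**
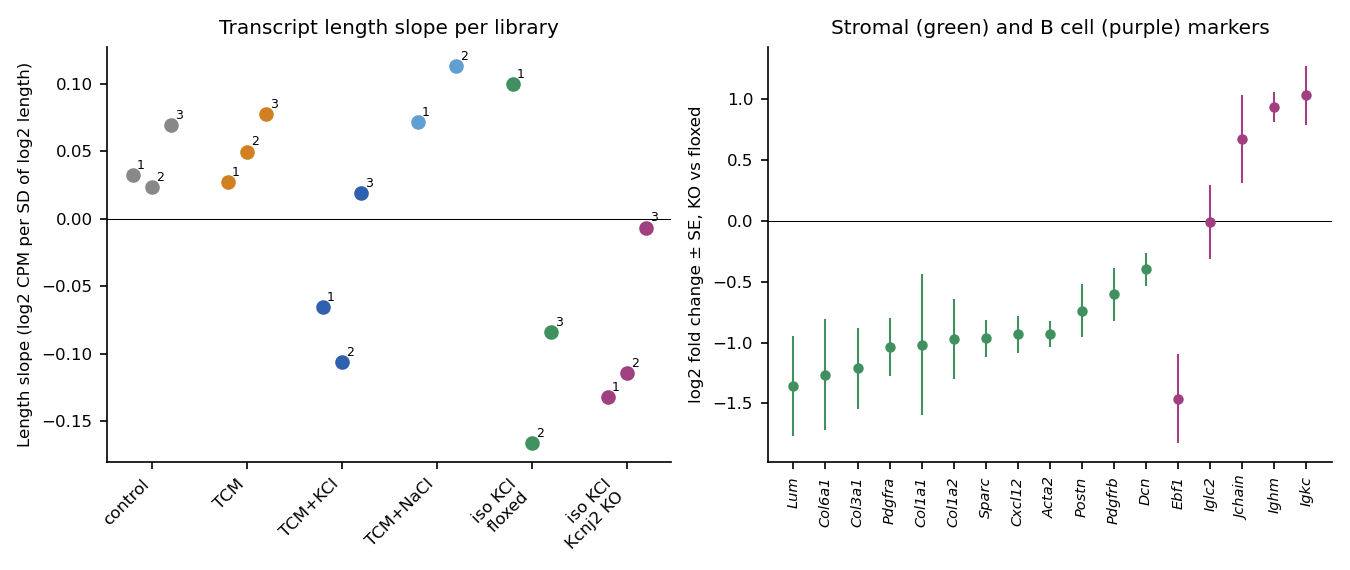
Left, the length slope of each library (log2 CPM per SD of log2 transcript length, numbers are replicates), which spans −0.17 to 0.10 within the floxed group. Right, log2 fold change with its SE in knockout against floxed cells for stromal markers (green, all 12 below 0) and B cell markers (purple, Igkc highest at 1.03).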

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

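The tests of the stromal and B cell markers and of the difference between the salts, and the use of the length slope as a covariate, were chosen only after the results were seen; those of the spread within groups and of the splits were chosen before theirs.

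Libraries of the same group differed mainly along 1 direction, which held 78.8% of the variance within groups over 8541 genes and whose gene weights correlated with transcript length across genes (Spearman's rho 0.30; genes are not independent replicates). Along this direction libraries spread widely only in the groups given KCl. Positions ran from −0.31 to 0.38 with KCl, −0.50 to 0.57 in floxed and −0.22 to 0.31 in knockout cells. They lay between −0.07 and 0.09 in control, conditioned medium and NaCl. The cause of this contrast was not tested. With every library thinned to the smallest total the range of length slopes in the floxed group stayed at 99.7% of its size. Random thinning keeps the expected share of each gene, so this cannot decide whether sequencing depth played a part. Without the 50 largest genes the range stayed at 100.6%, so the slopes did not rest on those genes themselves. Leaving them out rescales all other genes of a library alike, so it cannot decide whether a few genes taking most of the counts mattered. A bias of library preparation or RNA quality with transcript length is a candidate explanation: without genes of ribosomal proteins, oxidative phosphorylation, stroma and ribosome biogenesis the correlation was still 0.27. Adding the slope as a covariate took the biological coefficient of variation from 0.116 to 0.0629 in the C57BL/6J libraries and from 0.221 to 0.0610 in the isotonic ones, but there a stromal marker covariate took it to 0.0679 and a GC slope to 0.127, so the fall is not specific to length, and a change in the cells that tracks transcript length stays open.

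Knockout libraries had lower stromal markers than floxed libraries and a B cell list ranked higher. A length bias is argued against as the whole cause, since the stromal median was −0.91 with the slope as a covariate and −0.97 without it, with an adjusted p = 1.1e-40 at the preset correlation, though 0.182 with an estimated one. A lower share of macrophages would raise the markers of every other type, whereas the stromal list had a median of −0.97 with an SD of 0.27 over its 12 members and 11 of them were lower adjusted over the list alone; the 5 B cell markers went both ways (median 0.67, mean 0.23, Ebf1 at −1.46, and a median of 0.58 with an SD of 1.02 with the covariate). Fewer stromal cells in the knockout cultures is a candidate explanation: 18 of 18 further matrix genes were lower, with a median of −0.93 and an SD of 0.18 and 0 of them called, and with the covariate the median was −0.74 and 17 were called. Lower expression within cells of the same number stays open, as do differences between the mice used.

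KCl and NaCl differed in 4591 genes, of which 303 (6.6%) were called with the same direction once the length slope was a covariate. A length bias between these 5 libraries may account for much of the count, but the test cannot decide. Slopes did not overlap between the salts (−0.11 to 0.02 with KCl, 0.07 to 0.11 with NaCl). The covariate thus takes up part of any salt effect, and calls would be lost with either cause. A length bias is argued against as the whole cause for the genes raised by conditioned medium. Their median was −0.17 with the covariate (1409 genes chosen anew in that fit, camera adjusted p = 3.1e-06). The KCl and NaCl libraries also helped set the slope effect used in choosing those genes. A stronger osmotic response with KCl cannot be told apart from an equal one: the 17 NFAT5 targets had a median of −0.0457 between the salts with an SD of 0.49, 7 of them higher and 10 lower with KCl (adjusted p = 0.953), while with the covariate the list was higher with KCl (median 0.26, adjusted p = 0.00299, and 0.0895 with an estimated correlation). An effect of potassium apart from osmolarity stays open as the biological explanation.

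For groups of 3 and 3 libraries there are 10 splits, too few for a share under 0.05. In fits of the 6 libraries alone, conditioned medium against control gave 9259 genes and the highest other split 0, and KCl against conditioned medium gave 6512 and the highest other split 0. The knockout gave 2 genes against 0, and with the length slope as a covariate 1043 against 1. In each of these 4 cases 1 of the 10 splits, the real one, gave as many genes. Every other split mixes both groups on each side, so a true difference widens its spread and lowers its count. Low counts in the other splits thus do not show how many calls would arise without a true difference. With edgeR the unadjusted count in the knockout was 716, not far above that expected with no true change, and DESeq2 called 177.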

How the results depend on the processing

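Chosen only after the results were seen were total-count scaling, the 3 covariates and the fits without libraries of extreme length slope; all other settings were planned. Counts of changed genes for conditioned medium against control and KCl against conditioned medium stayed within 1.5 times of 7773 and 7830 in every setting but the 2-fold minimum, which by construction gave 3046 and 2759, with 1013 for NaCl, 881 for KCl against NaCl and 764 genes changed alike. These are totals, and the genes called can differ. With the length slope 7746 of the 7773 calls for conditioned medium stayed in the same direction, but only 4965 of the 7830 with KCl. RLE factors left 164 of 165 list calls and 161 of 162 named gene calls as they were, and DESeq2 159 of 160 named genes. For the changes below the cause was not tested. NaCl against conditioned medium gave 6245 genes when only the groups compared were fitted and 2224 to 3465 without a library. KCl against NaCl gave 8 genes when only its groups were fitted, 1299 with all 17 libraries, 525 with the length slope, 2359 with KCl library 3 alone and 960 to 6989 without a library. Genes changed alike numbered 2045 to 4012. The knockout gave 177 genes with DESeq2, 12 without a low-count filter, 272 with all 17 libraries, 0 with a replicate block (edgeR, 716 at unadjusted p without a block), 159 with the GC slope, 1043 with the length slope, 5624 with the stromal covariate, 40 without floxed library 1 and knockout library 3, and 0 to 14 without a library. Covariates take 1 of 4 residual degrees of freedom there, and the stromal one is itself a difference between the groups. Lists past the threshold, in the order of the report, numbered 28, 27, 21, 16 and 5 with fry, which does not compare a list with other genes, and 10, 2, 2, 0 and 0 with an estimated correlation. Without a low-count filter KCl had 12 and NaCl 10, with the length slope NaCl and KCl against NaCl had 8 each, and the knockout had 8 to 12 without a library. Each refit chose its sets anew, so their members can differ from the reported ones. With the length slope only 14 genes higher with KCl than NaCl were tested in the knockout, against 436, and 59 lower ones, against 317. In the knockout the genes higher with KCl than NaCl had a median of −0.0118 without a filter, 0.0089 with an estimated correlation, 0.22 with the length slope (those 14 genes) and −0.35 to 0.45 without a library, below 0 without floxed 1 (−0.35), knockout 1 (−0.15) or knockout 2 (−0.0752). The genes lower with KCl passed with a stricter filter (−0.17, adjusted p = 0.0415) and, for the 59 genes of that fit, with the length slope (−0.0174, adjusted p = 0.00954), and had −0.39 to 0.22 without a library. Genes raised by KCl passed with a block (0.0799, adjusted p = 0.0431) and had −0.19 to 0.26 without a library, and those lowered by it −0.13 to 0.0818. These 3 sets did not pass in the reported fit but did, in their first direction, without floxed 2 (adjusted p = 4.4e-09, 1.8e-09 and 0.0032) or knockout 3 (2.0e-06, 1.7e-05 and 0.0481). Without floxed 1 these 3 sets passed in the opposite direction (adjusted p = 3.1e-04, 3.1e-05 and 0.0193). The genes higher with KCl than NaCl did so there too (4.2e-11). Genes lowered by conditioned medium had 0.11 between the salts with the length slope (adjusted p = 0.0394). Signs turned in the knockout for oxidative phosphorylation, to −0.19 without floxed 1 (−0.19 to 0.36 without a library) and −0.0107 with the length slope. With the length slope signs also turned for Rn7sk (−0.40) and CT010467.1 (−0.36) with KCl, and between the salts for Nos2 (0.20), Wdr89 (−0.42), Rpl35a (−0.0744), Atp5e (−0.0627) and Atg9a (0.22). At these depths 0% of 1.5-fold changes and 39.1% of 2-fold changes were recovered by edgeR in simulations of the knockout. DESeq2 was not run for gene lists, as it gives no test of lists.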

Other observations

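No test of an explanation was made for the values in this part, and genes named here were chosen after their values were seen, as members of the fixed lists unless said otherwise. Fits without single libraries were not made for most of these genes.

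Genes of potassium channels and of sodium and potassium transport were mostly lower with KCl than in conditioned medium alone: 12 of 19 fell and 4 rose (14 and 4 adjusted over the list alone, median −0.86), though the list as a whole did not pass (camera adjusted p = 0.136). The channel subunit Kcne3 (−4.24), the channels Kcna3 (−3.48) and Kcnk12 (−2.48) and the lysosomal channel Tmem175 (−2.14) fell, while Kcnk13 (1.06) and Atp1b3 (0.91) rose. With NaCl 8 of 19 fell and 4 rose (10 and 4 adjusted over the list alone, median −0.62, adjusted p = 0.293), with Tmem175 at −1.31, Kcnk13 at 0.90 and Atp1b3 at 0.68. Conditioned medium itself raised Kcna3 (3.39) and lowered Slc5a3 (−2.21), the inositol transporter that both salts raised.

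KCl lowered several genes that conditioned medium had raised. The complement genes C3 (−1.53) and Cfb (−2.10) fell after rises of 2.72 and 4.04, and the anti-inflammatory cytokine Il10 (−2.77) after a rise of 2.25. The checkpoint ligand Cd274 (−0.90) and the chemokine Ccl22 (−1.13) fell after rises of 4.61 and 4.75. The hypoxia targets Pdk1 (−1.56) and Car9 (−2.16) fell with KCl, as did the complement receptor C5ar1 (−2.27), and the arginase Arg2 rose (2.35). With NaCl, Il10 (−2.49), C5ar1 (−1.06), Pdk1 (−1.04) and Car9 (−1.27) fell and Arg2 rose (1.92).

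With the length slope as a covariate in the knockout, the immunoglobulin genes Ighg1 (2.31), Ighg2b (1.18), Igkc (0.96) and Ighm (0.96) were higher, as were the interferon-responsive genes Ifi27l2a (1.17), Oas3 (0.92) and Ly6e (0.83), and the chemokines Ccl7 (−0.91), Cxcl10 (−0.83) and Ccl2 (−0.67) were lower. Ighg1, Ighg2b, Ifi27l2a, Ly6e and Ccl7 are in none of the fixed lists. Scgb1a1 was at 14.8 ± 1.85 CPM with KCl and 1.35 ± 0.535 CPM with NaCl. Lists whose median and mean differed in sign include MHC class II (0.18 and −0.09), p53 targets (−0.11 and 0.14) and lysosome (−0.09 and 0.08) in conditioned medium against control, and no list with such a difference passed the threshold.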
